A study of Homo sapiens with 24 samples.

How the data were processed

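RNA sequencing libraries from 3 cell lines, A375 (melanoma, in 2 batches), SK-Hep1 and SKBR3, were compared 48 hours after transfection with siRNA against GCDH or control siRNA. There were 24 libraries in 8 groups of 3, and groups and replicate numbers were taken from the sample labels. Per the labels' protocols, cells were seeded in triplicate wells, RNA was extracted with RNeasy columns and libraries were read single-end on an Illumina NextSeq. A375 batch 1 was made with a Lexogen QuantSeq kit that reads the 3' end of polyadenylated RNA, whereas A375 batch 2, SK-Hep1 and SKBR3 were made with poly(A) selection and a NEBNext Ultra II directional kit. Length-corrected values of a 3' tag library do not compare directly with those of a full-length library, and no level was tested between the kits.

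The deposited table holds TPM values made by the authors, 1 column per library and 60504 rows. Per the submitters' processing notes, cutadapt 2.3, STAR 2.7.0d, RSEM 1.3.1 and the hg38 build were used. RSEM divides reads among near-identical transcripts, so that pseudogenes, multicopy genes and short RNAs inside other genes are uncertain. The annotation version and the strand setting are not given in the sources used here. TPM values hold no read totals, so the depth of each library is unknown and no counting interval was given. Gene symbols were matched by identifier to a table of 56558 names, and 40283 rows had a symbol.

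Values were transformed to log2(TPM + 1). Each line and batch was fitted on its own 6 libraries with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3 with statmod 1.5.0, over genes with a mean of at least 1 TPM. P-values of two-sided tests were adjusted by the Benjamini-Hochberg method over the genes of a fit, and genes with an adjusted p under 0.05 were called. The mean of the within-batch effects and the difference between the batches were tested on the 12 A375 libraries. Differences between A375 batch 2 and each other line were tested as interactions on 12 libraries of the same kit. GCDH was also tested with an exact two-sided permutation test within each line and batch.

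Before the data were examined, 23 gene lists were fixed, covering lysine and tryptophan breakdown, NRF2 targets, the ATF4 response, ER chaperones, apoptosis, cell cycle, p53 targets, interferon, NF-kB, cholesterol synthesis, MAPK output, heat shock, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, autophagy, melanocyte and invasive melanoma genes, breast, hepatocyte and endothelial markers and non-polyadenylated histone genes. Lists with at least 5 tested genes were compared with the other genes by camera with its preset correlation of 0.01, adjusted over lists and the 4 within-line comparisons together (84 tests), or over the 21 or 22 lists of each other comparison, and camera with an estimated correlation and the directional fry test were run beside it. Of 84 tests within lines, 9 passed upward and 19 downward, none passed with the estimated correlation, and 61 passed by fry. The directional fry test does not compare a list with other genes.

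Genes were named by a rule fixed at the same time. It took GCDH, a panel of 7 genes (NFE2L2, ATF4, ATF3, DDIT3, CHAC1, TRIB3 and DHTKD1), the 8 largest rises and 8 largest falls among called genes with at least 5 TPM in the higher group and no overlap between the groups, and up to 3 called members of each list with the smallest adjusted p. For each difference it took the 5 largest in each direction. Genes without an approved symbol were skipped, and some genes taken by this rule are not reported here. Called genes were compared between within-line comparisons with Fisher's exact test per direction and with Spearman correlations across genes, adjusted over 12 tests.

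Alternatives were other pseudocounts (0.1 and 5), no filter or a filter at 5 TPM, quantile normalization, median scaling over genes of at least 5 TPM, eBayes without trend or robust, the replicate number as a block, a joint fit of all 24 libraries, ranking by size alone, and leaving out each library in turn. Alternatives added after the data were seen were removal of 5 chromosome 21 rows, removal of genes with a seed match, median scaling of the list tests, and the blocked and joint fits of GCDH. The fits were tested on simulated data in which 100 genes were changed by 0.5 and 100 by 1 on the log2 scale. Of the larger changes 5% were recovered in A375 batch 1, 80% in batch 2, 70% in SK-Hep1 and 84% in SKBR3, and of the smaller ones 0%, 41%, 31% and 44%. Fewer genes were changed there than were called in the data, so the adjustment was stricter and these shares may understate recovery.

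Annotated 3' UTRs of GENCODE 29 were searched for every 7-mer, in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, over genes with a mean of at least 5 TPM and a 3' UTR of at least 50 nt. Fold changes were first adjusted by regression on the length of the 3' UTR, its share of G and C bases and the mean TPM. They were then clipped at percentiles 1 and 99. For each of 15931 7-mers present in at least 50 genes, the adjusted fold changes of genes with and without it were compared as a z value. Genes with no annotated 3' UTR were not searched. Coordinates are 1-based on hg38. Figures were drawn with matplotlib 3.10.9.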

Results

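RNA was measured by sequencing in 3 human cancer cell lines transfected with small interfering RNA (siRNA) against GCDH or with a control siRNA and collected 48 hours later. GCDH encodes glutaryl-CoA dehydrogenase, a mitochondrial enzyme of lysine and tryptophan breakdown. The lines were A375, a melanoma line, SK-Hep1, labelled as a liver cancer line, and SKBR3, a breast cancer line known for an amplified ERBB2 gene. A375 was measured in 2 batches made with different library kits, so that 24 libraries fell into 8 groups of 3. Values are TPM, which correct for transcript length and sum to the same total in each library, and are given as mean ± SD over the 3 libraries of a group. The sequencing depth is unknown, because TPM values keep no read totals. Between 12349 and 17174 genes reached 1 TPM in a library, as group means. Replicates were triplicate wells, so the p-values reflect the spread between these wells, which may be technical. Correlations of log2 values between replicates ran from 0.906 to 0.925 in A375 batch 1 and from 0.968 to 0.979 in the other groups.

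The series asks how loss of GCDH acts on melanoma cells in comparison with other cancer cells, with the transcription factor NRF2 (gene NFE2L2) named in its title. The targeted transcript was therefore examined first. GCDH (ENSG00000105607, hg38 chromosome 19, 12891026 to 12914207, plus strand) was lower in every siGCDH library than in every siControl library of the same line and batch. In A375 batch 2 it went from 20.9 ± 1.71 to 3.72 ± 0.269 TPM (log2 fold change -2.21, SE 0.10, adjusted p = 1.41e-05). SK-Hep1 went from 9.41 ± 0.413 to 2.76 ± 0.50 TPM (log2 fold change -1.48, SE 0.14, adjusted p = 7.09e-05), and the libraries labelled SKBR3 from 22.5 ± 0.397 to 5.94 ± 1.52 TPM (log2 fold change -1.78, SE 0.15, adjusted p = 6.39e-05). In A375 batch 1 GCDH was near the low end of the measured range and had from 4.41 ± 2.48 to 0.917 ± 0.595 TPM, a log2 fold change of -1.42 that did not pass (limma adjusted p = 0.118). The residual level was 20.8% of siControl in A375 batch 1, 17.8% in batch 2, 29.3% in SK-Hep1 and 26.4% in SKBR3. An exact two-sided permutation test gave p = 0.1 in each of these 4 comparisons, the smallest p that 3 against 3 libraries allow.

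Libraries differed in features other than the targeted gene. In A375 batch 1, 5 lincRNA rows in a chromosome 21 region (8197620 to 8438551), 4 of which overlap 45S ribosomal RNA genes of RefSeq (GRCh38.p14), took 17.1 ± 2.07% of all TPM with siControl and 33.0 ± 1.65% with siGCDH, against less than 0.1% in each other group. The libraries labelled SKBR3 held ERBB2 at 25.5 ± 2.23 TPM with siControl, below A375 batch 2 (32.7 ± 1.72) and SK-Hep1 (46.4 ± 5.12), and the epithelial keratin KRT19 at 0.227 ± 0.393 TPM against 1262 TPM in SK-Hep1. Mitochondrially encoded transcripts went from 2.06 ± 0.0610% to 4.88 ± 0.109% of TPM in SKBR3, as shares without a test.

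**Figure D1:**
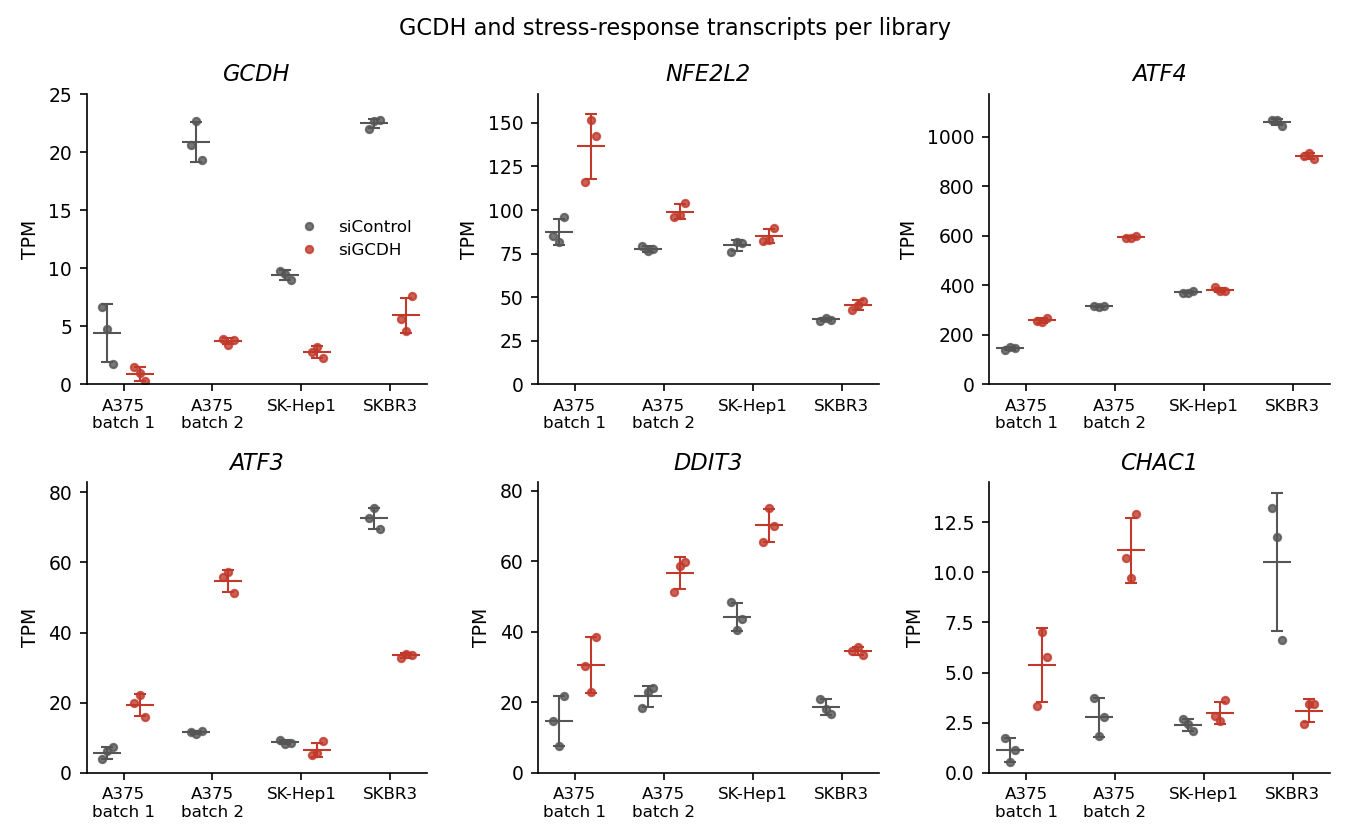
TPM of GCDH and 5 stress-response genes in each library (points), by line and batch on the x axis, with siControl in grey and siGCDH in red. Horizontal bars are group means and error bars 1 SD over 3 libraries. GCDH lies lower with siGCDH in all 4 comparisons, while ATF4 and ATF3 lie higher with siGCDH in both A375 batches and lower in SKBR3.

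In A375 batch 2, siGCDH was accompanied by higher transcripts of the p53 pathway and of the ATF4 branch of the integrated stress response, and by lower transcripts of NRF2 targets and of the respiratory chain. These list calls rest on camera with its preset correlation, and none of them passed with an estimated one. CDKN1A, the cell cycle inhibitor p21, went from 156 ± 4.89 to 468 ± 13.4 TPM (log2 fold change 1.58, SE 0.04, adjusted p = 1.01e-06). ATF4, the transcription factor of the amino acid and unfolded protein stress responses, went from 315 ± 0.98 to 595 ± 5.08 TPM (log2 fold change 0.92, SE 0.03, adjusted p = 2.35e-06), and its partner ATF3 from 11.6 ± 0.405 to 54.8 ± 3.19 TPM (log2 fold change 2.15, SE 0.07, adjusted p = 2.99e-06). NFE2L2 itself rose from 77.7 to 99.1 TPM (0.35), while ferritin heavy chain FTH1 fell from 5965 to 3042 TPM (-0.97). limma with Benjamini-Hochberg adjustment called 5099 of 15185 tested genes, 2715 higher and 2384 lower, and 292 and 225 of these changed by at least 1 on the log2 scale. After each library was scaled to a common median, the calls were 2612 higher and 2538 lower. Fold changes are on the log2(TPM + 1) scale and understate the change of low genes.

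The 8 largest rises in batch 2 were led by KRTAP2-3, a keratin-associated protein gene, which went from 1.95 ± 0.357 to 45.2 ± 1.45 TPM (log2 fold change 3.98, SE 0.11, adjusted p = 1.91e-06). S1PR1, a sphingosine-1-phosphate receptor, rose from 1.5 to 11.6 TPM (2.33) and the serpin SERPINB7 from 8.6 to 43.1 TPM (2.19). LINC00973, a long non-coding RNA, rose from 8.19 to 44 TPM (2.31). The other 4 were IGKV1OR9-2 (3.34), MIR6807 (3.04), RNA5SP244 (2.9) and WASH7P (2.29), whose values are uncertain because short RNAs and near-identical copies share reads. Among the 8 largest falls, HNRNPC, which encodes an abundant nuclear RNA-binding protein, fell from 856 ± 9.71 to 130.1 ± 4.12 TPM (log2 fold change -2.71, SE 0.04, adjusted p = 5.62e-08). The chemokine gene CCL2 fell from 50.8 to 9.76 TPM (-2.28) and SERPINA3, alpha-1-antichymotrypsin, from 252 to 56 TPM (-2.15). TKT, transketolase of the pentose phosphate pathway, fell from 916 to 197 TPM (-2.21), CYRIB, a RAC1-binding protein, from 124 to 25 TPM (-2.27) and the kinase gene NEK7 from 41.7 to 8.65 TPM (-2.16). The 3' UTRs of TKT, CYRIB and NEK7 hold ACTGAGA, the 7-mer with the lowest z of 15931 searched in batch 2, and those of HNRNPC, CCL2, SERPINA3 and BPHL do not. It was held by 1406 of the 10044 genes searched in batch 2. BPHL, a hydrolase gene, fell from 12 to 2.0 TPM (-2.12), and GCDH completed the 8.

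Of 23 measured p53 targets, 18 rose, 0 fell and 5 did not pass (adjusted over the list alone, 18 rose and 0 fell). The list stood above other genes (median 0.59, camera adjusted p = 1.87e-11, and adjusted p = 0.0593 with an estimated correlation). GADD45A rose by 1.72 and MDM2, the p53 ubiquitin ligase, by 1.57. Of 34 genes of the ATF4 list, 22 rose, 4 fell and 8 did not pass (adjusted over the list alone, 23 rose and 4 fell) (median 0.36, camera adjusted p = 6.34e-07, and adjusted p = 0.0593 with an estimated correlation). DDIT3, which encodes CHOP, rose from 21.7 to 56.6 TPM (1.35), the glutathione-degrading enzyme gene CHAC1 from 2.76 to 11.1 TPM (1.71), PPP1R15A from 55.6 to 113 TPM (1.01) and TRIB3 from 45 to 53.2 TPM (0.24), a call lost without the trend, and without siControl replicate 2 or 3 or siGCDH replicate 1 or 3. Among pro-apoptotic genes 9 rose and 1 fell (9 and 1 adjusted over the list alone) of 19 (median 0.29, camera adjusted p = 0.0142, and adjusted p = 0.351 with an estimated correlation), with BBC3, which encodes PUMA, at 1.44, BAX at 0.59 and FAS at 0.85, and the list call was lost when genes with a seed-match 7-mer in the 3' UTR were left out. BBC3, BAX, FAS and TNFRSF10B are members of both the pro-apoptotic and the p53 list, so the calls of these lists are not independent. BAX, FAS and MDM2 rose although their 3' UTRs hold ACTGAGA or the shifted 7-mer CTGAGAA. MAPK output genes also stood higher (10 rose and 3 fell (13 and 3 adjusted over the list alone) of 20, median 0.24, camera adjusted p = 0.0225, and adjusted p = 0.574 with an estimated correlation), led by EGR1 (1.93), DUSP5 (1.1) and FOSL1 (1.02).

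The NRF2 list moved downward in batch 2. Of 33 measured targets, 5 rose, 20 fell and 8 did not pass (adjusted over the list alone, 5 rose and 20 fell) (median -0.37, camera adjusted p = 3.37e-06, and adjusted p = 0.0593 with an estimated correlation). FTH1 fell by 0.97 on the log2 scale and the peroxidase gene PRDX1 from 1167 to 664 TPM (-0.81). TKT, which also fell, belongs to the same list. HMOX1, another member, rose in batch 2, with its values given under the other observations. TKT and PRDX1 carry ACTGAGA, and FTH1 does not. Nuclear-encoded oxidative phosphorylation genes showed no rise and 18 of 31 fell (median -0.15, camera adjusted p = 4.83e-06, and adjusted p = 0.233 with an estimated correlation), among them UQCRC1 of complex III (-0.97) and COX5A of complex IV (-0.49). Cell cycle genes had 6 rose and 21 fell (8 and 22 adjusted over the list alone) of 36 (median -0.25, camera adjusted p = 0.00108, and adjusted p = 0.127 with an estimated correlation), with the replication factor gene MCM3 at -0.79, CENPF at -0.74 and CCNB1 at -0.54. Of the cholesterol and SREBP list 4 rose and 10 fell (4 and 10 adjusted over the list alone) of 25 (median -0.15, camera adjusted p = 0.00813, and adjusted p = 0.351 with an estimated correlation). Its most significant members were SCD, the stearoyl-CoA desaturase gene (-1.42), ACLY (-0.75) and FDFT1 (-0.46). In the interferon list 0 rose and 6 fell (0 and 6 adjusted over the list alone) of 23 (median -0.07, camera adjusted p = 0.0456, and adjusted p = 0.233 with an estimated correlation), with IFIT2 at -1.19 and OAS3 at -0.66, a list call lost without seed-match genes, with quantile normalization, with the replicate block, and without siControl replicate 2 or 3 or siGCDH replicate 1 or 2.

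The other lists did not pass in batch 2. In the pathway of GCDH itself, ALDH7A1, the aminoadipate semialdehyde dehydrogenase of lysine breakdown, fell from 113 to 50.4 TPM (-1.16) and the electron-transfer flavoprotein gene ETFB fell from 234 to 159 TPM (-0.55), whereas DHTKD1 had from 19.6 ± 1.48 to 20.9 ± 4.32 TPM and did not pass (adjusted p = 0.731). That list had 2 rose and 5 fell (2 and 6 adjusted over the list alone) of 18, and its median (0.02) differed in sign from its mean (-0.17) and test (camera adjusted p = 0.399). ER chaperones had 13 rose and 4 fell (13 and 4 adjusted over the list alone) of 25 (camera adjusted p = 0.0695), with CALR, calreticulin, which holds ACTGAGA, at -2.02, and CANX, calnexin (0.74), and PDIA6 (0.48) higher. Anti-apoptotic genes had 3 rose and 3 fell (3 and 3 adjusted over the list alone) of 11, and heat shock genes 7 rose and 3 fell (7 and 3 adjusted over the list alone) of 16. Glycolysis and hypoxia genes had 6 rose and 10 fell (6 and 12 adjusted over the list alone) of 27, and NF-kB genes 7 rose and 4 fell (8 and 6 adjusted over the list alone) of 19. In the anti-apoptotic list MCL1 (0.41) and BCL2L1 (0.49) rose and BIRC5 (-0.66) fell. Autophagy genes had 8 rose and 8 fell (9 and 10 adjusted over the list alone) of 26, with a median of 0.06, a mean of -0.05 and a test pointing down (adjusted p = 0.893). BECN1, which carries ACTGAGA, fell by 1.49, and GABARAPL1 rose by 0.79. In the melanocyte list 3 rose and 2 fell (3 and 2 adjusted over the list alone) of 10, with the lineage factor gene MITF at 0.87 and S100B at -1.16. The invasive melanoma list had 9 rose and 2 fell (10 and 3 adjusted over the list alone) of 20, including the receptor kinase gene AXL (1.17) and JUN (1.73). Mitochondrially encoded genes had 3 rose and 5 fell (3 and 6 adjusted over the list alone) of 13, breast epithelial markers 1 rose and 3 fell (1 and 3 adjusted over the list alone) of 8, and non-polyadenylated histone genes 4 rose and 1 fell (4 and 1 adjusted over the list alone) of 11.

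In A375 batch 1, measured with a 3' tag kit, transcripts of the respiratory chain, the mitochondrial genome and NRF2 targets were lower with siGCDH, and p53 targets were higher. These list calls rest on camera with its preset correlation, and none of them passed with an estimated one. HNRNPC fell from 454 ± 56.8 to 60.8 ± 9.04 TPM (log2 fold change -2.88, SE 0.14, adjusted p = 4.31e-04), CCL2 fell from 24.2 to 2.56 TPM (-2.87), and CALR fell from 259 to 48.5 TPM (-2.42). KRTAP2-3 rose from 1.38 ± 1.71 to 37.5 ± 2.99 TPM (log2 fold change 4.27, SE 0.48, adjusted p = 0.00478) and CDKN1A from 68.8 to 144 TPM (1.06). Of the stress panel, ATF4 (0.83), ATF3 (1.62), CHAC1 (1.57) and NFE2L2 (0.63) rose. With the replicate number as a block the calls of ATF3, CHAC1 and NFE2L2 were lost. CHAC1 was also lost after median scaling and with each library left out in turn. NFE2L2 was lost with each library left out except siGCDH replicate 1, and ATF3 only without that library. Without the mean-variance trend none of these calls passed. Of the other genes named for batch 1, KRTAP2-3, RNF166, HNRNPC, CCL2, CALR, TAC1, ALDH7A1, PRDX1, FTH1 and SCD passed without the trend and the rest did not. DDIT3 (1.08, adjusted p = 0.118), TRIB3 (-0.06, 0.896) and DHTKD1 (-0.41, 0.404) did not pass. limma called 1018 of 12868 genes, 152 higher and 866 lower, with 97 and 403 changed by at least 1. The median of all tested genes moved by -0.20, and the chromosome 21 rows took a larger share of TPM with siGCDH. With the median scaled out the calls were 218 higher and 277 lower, and with those 5 rows removed and TPM rescaled, an alternative chosen after the data were seen, 293 higher and 229 lower. Simulated changes of 1 log2 unit were recovered for 5% of genes in this batch, against 80% in batch 2. The simulation changed far fewer genes than were called in the data, which makes the adjustment stricter, so these shares may understate recovery. Leaving out any single library gave between 311 and 592 called genes.

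The other large rises in batch 1 were MYLK, the smooth muscle myosin light chain kinase gene (2.46), WFDC3 (2.38), ZNF544 (2.03), the non-coding LINC02484 (2.33) and LINC01060 (1.95), and RPL32P24 (2.52) and FAM88C (1.94), the former a pseudogene of uncertain counting. The largest falls were RNF166, a ubiquitin ligase gene (from 18.1 to 0.877 TPM, -3.43), the cancer-testis gene SSX2 (from 14.9 to 0.577 TPM, -3.26), HEXIM2-AS1 (-3.17), HNRNPC, CCL2, ATXN2L (-2.75), the tachykinin gene TAC1 (-2.64), whose 3' UTR alone among those searched holds ACTGAGA, and TK2, mitochondrial thymidine kinase (-2.62). SSX2 has near-identical copies, and its level is uncertain.

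Of 31 respiratory chain genes in batch 1, 0 rose, 19 fell and 12 did not pass (adjusted over the list alone, 0 rose and 24 fell) (median -0.59, camera adjusted p = 6.13e-11, and adjusted p = 0.0593 with an estimated correlation), among them UQCRB (-0.84) and ATP5F1B (-0.60). Mitochondrially encoded genes had 0 rose and 9 fell (0 and 11 adjusted over the list alone) of 13 (median -0.71, camera adjusted p = 6.98e-07, and adjusted p = 0.388 with an estimated correlation), including MT-ND4L (-0.71), MT-ND3 (-0.76) and MT-ND4 (-0.77). Of 31 NRF2 targets, 0 rose, 11 fell and 20 did not pass (adjusted over the list alone, 0 rose and 13 fell) (median -0.59, camera adjusted p = 1.27e-05, and adjusted p = 0.222 with an estimated correlation). They included PRDX1 from 1273 to 532 TPM (-1.26), FTH1 from 4083 to 1765 TPM (-1.21) and ferritin light chain FTL from 1213 to 640.3 TPM (-0.92). Glycolysis genes had 0 rose and 4 fell (0 and 6 adjusted over the list alone) of 27 (median -0.47, camera adjusted p = 0.00108, and adjusted p = 0.351 with an estimated correlation), with ALDOA at -0.92, PGK1 at -0.62 and TPI1 at -0.47. PGK1 and TPI1 no longer passed after median scaling, and the direction of both stayed downward. Of 22 p53 targets, 5 rose, 0 fell and 17 did not pass (adjusted over the list alone, 9 rose and 0 fell) (median 0.50, camera adjusted p = 1.96e-07, and adjusted p = 0.0851 with an estimated correlation), with GADD45A at 1.09 and RPS27L at 0.61. Non-polyadenylated histone genes had 1 rose and 1 fell (1 and 1 adjusted over the list alone) of 10 (median 0.22, camera adjusted p = 0.0211, and adjusted p = 0.233 with an estimated correlation), with H4C3 at 0.81, a list call lost without seed-match genes. The ATF4 list had 5 rose and 3 fell (5 and 4 adjusted over the list alone) of 32, with a median of -0.06 and a mean of 0.12 (camera adjusted p = 0.0537), and passed upward after median scaling.

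No other list passed in batch 1. Counts of rises and falls, with those adjusted over the list alone in parentheses, were 0 and 2 (0 and 2) of 17 for lysine and tryptophan breakdown, 1 and 1 (1 and 2) of 24 for ER chaperones, 1 and 0 (0 and 0) of 18 for pro-apoptotic genes, 0 and 0 (0 and 0) of 11 for anti-apoptotic genes and 1 and 4 (1 and 6) of 35 for cell cycle genes. They were 0 and 1 (0 and 1) of 18 for interferon genes, 0 and 4 (0 and 4) of 17 for NF-kB genes, 0 and 6 (0 and 6) of 25 for cholesterol and SREBP genes, 2 and 1 (2 and 1) of 20 for MAPK output genes and 1 and 4 (2 and 4) of 16 for heat shock genes. The remaining counts were 1 and 2 (2 and 4) of 25 for autophagy genes, 0 and 0 (0 and 0) of 9 for melanocyte genes, 1 and 1 (1 and 1) of 19 for invasive melanoma genes and 0 and 3 (0 and 3) of 8 for breast marker genes. Named members past the threshold were ALDH7A1 (-1.55) and ETFA (-1.13) of lysine and tryptophan breakdown, SHMT2 (-1.23) of the ATF4 list, CANX (0.87), BBC3 (0.89), RRM2 (-1.31), CDC20 (-0.82), CCND1 (0.90), IFI6 (-1.13), IER3 (-0.93) and CXCL8 (-1.12). From the lipid list came SCD (-1.65), SREBF1 (-1.2) and FDFT1 (-0.78). From the remaining lists came EGR1 (1.26), HSPA8 (-0.74), HSPB1 (-0.48), HSPH1 (0.47), ATG12 (1.09), BECN1 (-1.13), SQSTM1 (-0.59), ANKRD1 (1.51), TGFBI (-1.01), KRT8 (-1.79), KRT18 (-1.25) and TFAP2B (-1.21). The 3' UTRs of SHMT2, SCD, SQSTM1, TFAP2B and RPS27L, as well as that of MYLK among the rises, hold ACTGAGA or CTGAGAA. The medians of the ER chaperone (-0.04), interferon (-0.21), MAPK (-0.19) and heat shock (-0.13) lists lay below 0, while their camera tests, which compare a list with other genes, pointed up without passing.

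With both A375 batches in 1 model, the mean of the within-batch effects passed for 3463 of 14764 genes, 1080 higher and 2383 lower (1460 and 1584 after median scaling). The within-batch calls were 1018 and 5099. Here 3 lists passed with the estimated correlation as well, adjusted over the 21 lists of this model, whereas tests within a batch or line were adjusted over 84. Of 23 p53 targets 13 rose and 0 fell (14 and 0 adjusted over the list alone) (median 0.41, camera adjusted p = 6.02e-12, and adjusted p = 0.0114 with an estimated correlation). Respiratory chain genes had 0 rose and 21 fell (0 and 24 adjusted over the list alone) of 31 (median -0.36, camera adjusted p = 8.11e-12, and adjusted p = 0.0114 with an estimated correlation), and NRF2 targets 1 rose and 17 fell (1 and 20 adjusted over the list alone) of 32 (median -0.43, camera adjusted p = 3.38e-07, and adjusted p = 0.0172 with an estimated correlation). The ATF4 list had 11 rose and 4 fell (13 and 4 adjusted over the list alone) of 34 (median 0.16, camera adjusted p = 1.00e-04, and adjusted p = 0.128 with an estimated correlation). HNRNPC (-2.8), TKT (-2.1) and KRTAP2-3 (4.12) passed in this model. GCDH averaged -1.82 (SE 0.24, adjusted p = 2.93e-04), within-batch values being -1.42 and -2.21.

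The effect of siGCDH differed between the batches for 772 genes, 706 with the higher value in batch 2. The median difference over all genes was 0.19, and the excess toward batch 2 depended on scaling. After median scaling 102 genes were higher and 83 lower in batch 2, after quantile normalization 100 and 122, and with the chromosome 21 rows removed 73 and 111. The count was 225 without the trend and 1190 without siControl replicate 1 of batch 1, and lay between 261 and 327 without any single library of batch 2. The largest differences were HEXIM2-AS1, RNF166, IGKV1OR9-2, MIR6807 and SSX2, with 3.62, 3.38, 3.34, 3.04 and 2.87 log2 units higher in batch 2. For IGKV1OR9-2 and MIR6807 the difference equals the rise in batch 2 to the digits given. Their change in batch 1 was thus about 0, which rows not detected there would also give. In the other direction they were RPL32P24, MCEE, PRR11-AS1, CKMT2-AS1 and L3MBTL3, with -3.19, -2.2, -1.99, -1.99 and -1.77. GCDH did not differ beyond the test (adjusted p = 0.41), nor did ATF4 (0.585), ATF3 (0.31) or NFE2L2 (0.314). Batch and library kit changed together and cannot be separated.

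**Figure D2:**
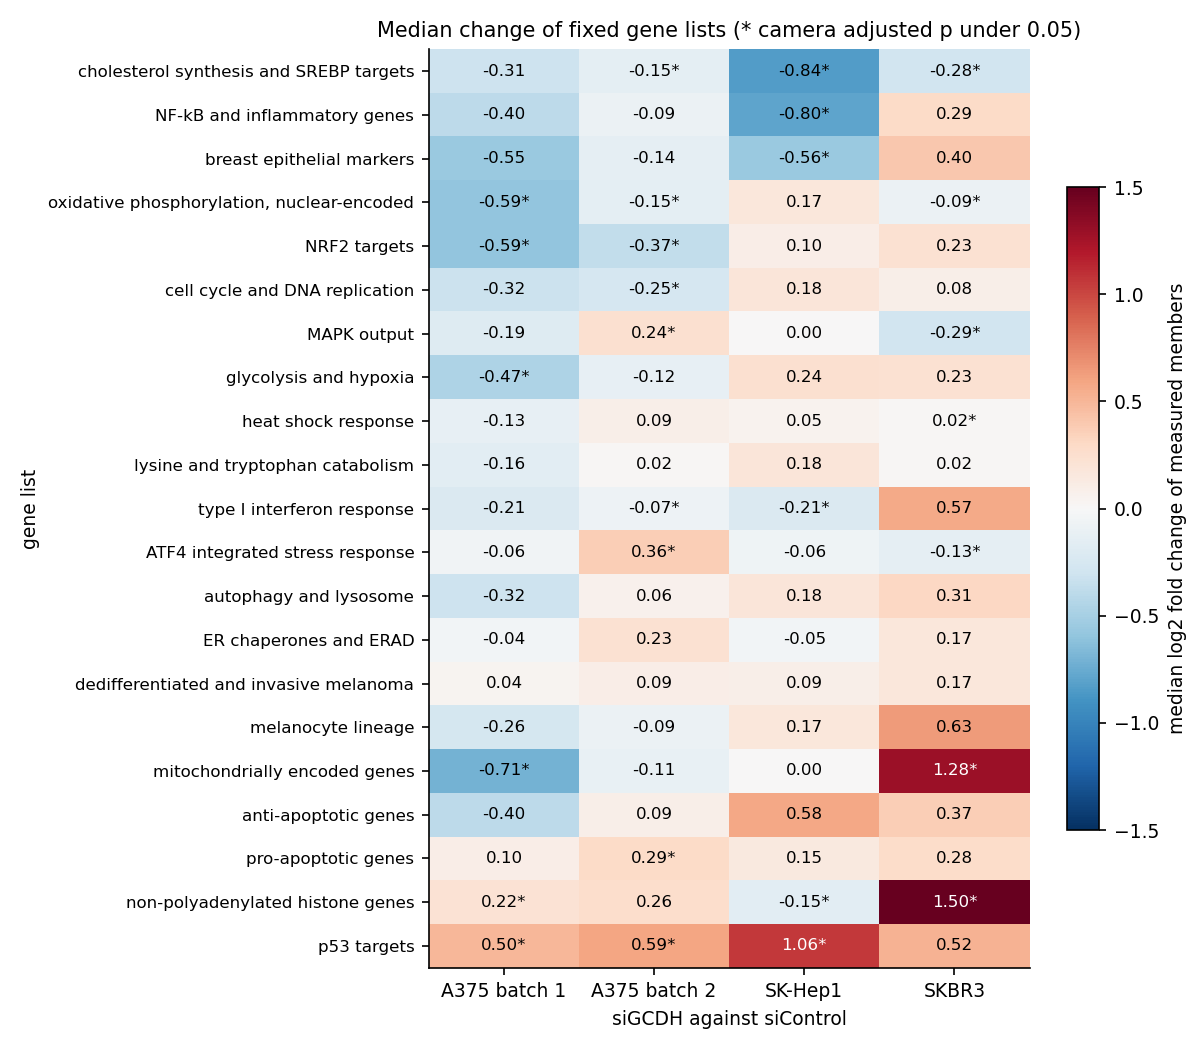
Median log2 fold change of the measured members of each gene list (y axis) with siGCDH against siControl in each comparison (x axis), coloured from blue (lower) to red (higher), with an asterisk where camera with its preset correlation passed. P53 targets have medians of 0.50 and 0.59 in the A375 batches, 1.06 in SK-Hep1 and 0.52 in SKBR3, and the ATF4 list has 0.36 in A375 batch 2 and -0.13 in SKBR3.

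In SK-Hep1, siGCDH was accompanied by lower cholesterol synthesis genes and SREBP targets, lower NF-kB and inflammatory genes, and higher p53 targets. These list calls rest on camera with its preset correlation, and none of them passed with an estimated one. SCD fell from 798 ± 17.7 to 197 ± 10.4 TPM (log2 fold change -2.01, SE 0.05, adjusted p = 1.87e-07), and ACLY, which supplies cytosolic acetyl-CoA, from 248 ± 3.9 to 44.1 ± 4.78 TPM (log2 fold change -2.47, SE 0.08, adjusted p = 7.35e-07). IL6 fell from 34.8 to 5.32 TPM (-2.5) and CCL2 from 17.7 to 1.45 TPM (-2.94), while GDF15, a secreted stress cytokine, rose from 58 ± 1.19 to 323 ± 14.2 TPM (log2 fold change 2.46, SE 0.05, adjusted p = 1.29e-07). Neither ATF4 (0.04, adjusted p = 0.398) nor NFE2L2 (0.09, 0.212) passed. limma called 8076 of 14557 genes, 5432 higher and 2644 lower, 784 and 518 of them by at least 1. The median of all genes moved by 0.18, and with the median scaled the calls were 3849 higher and 3559 lower. Ribosomal protein transcripts went from 18.9 ± 0.258% to 15.8 ± 0.646% of TPM.

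The largest rises in SK-Hep1 were the cation channel gene TRPV2 (from 7.96 to 77.3 TPM, 3.14), DMBT1 (from 2.64 to 28.6 TPM, 3.03), ZACN (2.58), the lysosomal glycoprotein gene CD68 (from 61.5 to 362 TPM, 2.54), GDF15, LINC02298 (2.4), the integrin gene ITGB2 (2.39) and FMC1 (2.35). The largest falls were ELF3, an epithelial transcription factor gene (from 52.5 to 3.43 TPM, -3.62), SNORD83A, which was listed at 0 in all siGCDH libraries against 9.93 ± 3.40 TPM, CXCL6 (from 35.8 to 2.51 TPM, -3.39), ATP5MC2, a subunit of the ATP synthase ring (from 744 to 88 TPM, -3.07), RPL22L1 (from 545 to 67.7 TPM, -2.99), HMOX1, heme oxygenase (from 41.4 to 4.54 TPM, -2.95), CCL2 and PADI2 (from 12.8 to 0.897 TPM, -2.87). The 3' UTRs of ELF3, RPL22L1 and HMOX1 hold the 7-mer ATCCTCA and that of CXCL6 the shifted TCCTCAA, but those of ATP5MC2, CCL2 and PADI2 hold neither. SNORD83A lies within a ribosomal protein gene, whose reads it can share.

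Of 25 cholesterol and SREBP genes, 1 rose, 21 fell and 3 did not pass (adjusted over the list alone, 1 rose and 22 fell) (median -0.84, camera adjusted p = 1.52e-13, and adjusted p = 0.0593 with an estimated correlation). Of 18 NF-kB genes, 1 rose, 13 fell and 4 did not pass (adjusted over the list alone, 1 rose and 14 fell) (median -0.80, camera adjusted p = 1.13e-07, and adjusted p = 0.0593 with an estimated correlation). CXCL1 fell from 135 to 43.3 TPM (-1.62), and IL1B went the other way, from 165 to 359.7 TPM (1.12). Of 24 p53 targets, 23 rose, 0 fell and 1 did not pass (adjusted over the list alone, 23 rose and 0 fell) (median 1.06, camera adjusted p = 2.41e-08, and adjusted p = 0.0593 with an estimated correlation), with CDKN1A at 1.33, BAX at 1.18 and the DNA repair gene DDB2 at 1.37. Interferon genes had 2 rose and 10 fell (2 and 10 adjusted over the list alone) of 23 (median -0.21, camera adjusted p = 0.00571, and adjusted p = 0.231 with an estimated correlation), with OAS3 (-1.25), IFI44 (-1.09) and PARP9 (-0.77) lower. Epithelial markers had 3 rose and 6 fell (3 and 6 adjusted over the list alone) of 11 (median -0.56, camera adjusted p = 0.0142, and adjusted p = 0.317 with an estimated correlation), with KRT8 from 2317 to 949 TPM (-1.29) and KRT18 from 2687 to 1109 TPM (-1.28). Non-polyadenylated histone genes had 1 rose and 4 fell (1 and 4 adjusted over the list alone) of 9 (median -0.15, camera adjusted p = 0.0455, and adjusted p = 0.245 with an estimated correlation), led by H2BC12 (-2.72), H2AC6 (-1.83) and H4C8 (-1.26). The histone call was lost after median scaling and quantile normalization, with the replicate block and without siGCDH replicate 2. Without seed-match genes the interferon, epithelial and histone calls were lost, and with quantile normalization the epithelial call as well.

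NRF2 targets were divided in SK-Hep1: 11 rose and 12 fell (12 and 12 adjusted over the list alone) of 29 (camera adjusted p = 0.0878), with a median of 0.10 and a mean of -0.28. TKT fell from 924 to 483 TPM (-0.94). The ATF4 list had 9 rose and 13 fell (10 and 13 adjusted over the list alone) of 31, a median of -0.06 and a mean of 0.01 (camera adjusted p = 0.217), with the amino acid transporter gene SLC7A5 at -1.91, TRIB3 at -0.61, PPP1R15A at 1.64 and DDIT3 at 0.66. ATF3 (-0.41, adjusted p = 0.1), CHAC1 (0.24, 0.273) and DHTKD1 (-0.02, 0.934) did not pass, though ATF3 was lower past the threshold after median scaling and quantile normalization. Counts of rises and falls in the other lists that did not pass, with those adjusted over the list alone in parentheses, were 9 and 2 (9 and 2) of 20 for lysine and tryptophan breakdown, 4 and 9 (4 and 9) of 25 for ER chaperones, 7 and 2 (5 and 2) of 19 for pro-apoptotic genes and 8 and 2 (9 and 2) of 11 for anti-apoptotic genes. They were 19 and 8 (19 and 9) of 36 for cell cycle genes, 6 and 5 (6 and 5) of 19 for MAPK output genes, 6 and 4 (6 and 4) of 16 for heat shock genes and 14 and 6 (14 and 6) of 26 for glycolysis and hypoxia genes. The remaining counts were 3 and 4 (3 and 4) of 13 for mitochondrially encoded genes, 13 and 4 (13 and 4) of 26 for autophagy genes, 0 and 0 (0 and 0) of 6 for melanocyte genes and 7 and 8 (8 and 8) of 20 for invasive melanoma genes. ALDH7A1 rose from 116 to 202 TPM (0.80) and ETFB from 63.6 to 103 TPM (0.69). Other named members were CALR (-0.69), HSP90B1 (-0.64) and DNAJB11 (1.0) of the ER list, and from the apoptosis lists TNFRSF10B (1.08), BBC3 (0.88), BIRC5 (0.74), BCL2L1 (0.68) and MCL1 (0.58). Of the cell cycle list they were CCND1 (1.58), TOP2A (0.92) and UHRF1 (-1.53). MYC fell by 1.35 and FOSL1 rose by 0.87. HSPA8 (-0.57), HSP90AB1 (-0.59) and HSPA4L (1.23) were the heat shock genes named, and ENO1 (-1.05), LDHA (-0.83) and ADM (-1.85) the glycolysis and hypoxia genes, whose list had a median of 0.24 (camera adjusted p = 0.782). FN1, fibronectin (-1.82), THBS1 (-1.23) and CAV1 (-0.95) fell. In the respiratory chain list 17 rose and 2 fell (17 and 2 adjusted over the list alone) of 31 (camera adjusted p = 0.0881), with COX7A2 (0.64), NDUFA4 (0.55) and SDHA (0.47) as its most significant members. For the MAPK, heat shock, mitochondrially encoded and invasive melanoma lists in SK-Hep1 the median was above 0 and camera pointed down without passing, and the mean of the invasive melanoma list was -0.20. Hepatocyte and endothelial markers had fewer than 5 measured genes in each line and were not tested there. Endothelial markers could be tested only for the difference between A375 batch 2 and SKBR3 and did not pass.

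In the libraries labelled SKBR3, siGCDH was accompanied by higher transcripts of the mitochondrial genome and of the non-polyadenylated histone list, measured in poly(A)-selected libraries, and by lower transcripts of ATF4 targets, cholesterol synthesis and MYC. These list calls rest on camera with its preset correlation, and none of them passed with an estimated one. MT-ND1 rose from 849.6 ± 12.3 to 2467 ± 32.6 TPM (log2 fold change 1.54, SE 0.02, adjusted p = 7.65e-08). MYC fell from 168 ± 1.94 to 36.8 ± 0.945 TPM (log2 fold change -2.16, SE 0.04, adjusted p = 2.20e-07), PSAT1, a serine synthesis gene, from 369.7 to 128 TPM (-1.52) and SLC7A5 from 124 to 32.3 TPM (-1.91). ATF4 fell from 1061 to 922 TPM (-0.20), a call lost with quantile normalization, ATF3 from 72.6 to 33.5 TPM (-1.09) and CHAC1 from 10.5 to 3.11 TPM (-1.45). limma called 10236 of 16494 genes, 7805 higher and 2431 lower, 2280 and 288 of them by at least 1. The median of all genes moved by 0.29, and calls after median scaling were 5376 higher and 3867 lower. With quantile normalization they were 4238 higher and 4309 lower, so that the excess of higher calls depended on scaling. In the same libraries lincRNAs outside the chromosome 21 region went from 0.509 ± 0.00867% to 1.01 ± 0.0101% of TPM, antisense RNAs from 0.712 ± 0.00850% to 1.23 ± 0.0106%, and ribosomal protein transcripts from 24.7 ± 0.202% to 20.2 ± 0.210%.

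Among the largest rises in SKBR3, EIF5-DT (from 2.39 to 48 TPM, 3.93), STAM-DT (from 1.46 to 30.1 TPM, 3.66), LINC01976 (from 5.09 to 72.7 TPM, 3.6) and LINC01238 (3.2) are non-coding, and H3C10 (from 2.02 to 37.4 TPM, 3.67) and H2BC21 (from 2.04 to 33.3 TPM, 3.5) are histone genes. DYNLT2 rose by 3.47 and CBY3 by 3.19. The largest falls were SNHG29, a small nucleolar RNA host gene (from 1079 to 99.6 TPM, -3.42), SLC25A6, a mitochondrial ADP/ATP carrier gene (from 541 to 56.2 TPM, -3.24), the ribosomal protein genes RPL13A (from 4013 to 561 TPM, -2.84) and RPS14 (from 3255 to 501 TPM, -2.69), ANAPC11 (from 267 to 44.9 TPM, -2.54) and SLC35F1 (-2.51), and the pseudogenes RPL13AP5 (-2.87) and COX7CP1 (-2.48), whose reads can come from their parent genes. SLC25A6, RPS14 and SLC35F1 hold ATCCTCA or TCCTCAA in their 3' UTRs, and RPL13A and ANAPC11 do not.

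All 13 mitochondrially encoded genes rose (median 1.28, camera adjusted p = 2.86e-08, and adjusted p = 0.245 with an estimated correlation), with MT-CYB at 1.5 and MT-ATP6 at 1.3. Non-polyadenylated histone genes, which poly(A) selection largely removes, had 9 rose and 1 fell (9 and 1 adjusted over the list alone) of 10 (median 1.5, camera adjusted p = 0.0256, and adjusted p = 0.233 with an estimated correlation), with H1-2 at 1.54, a list call lost without seed-match genes, without siControl replicate 1 and without siGCDH replicate 3. The antisense and lincRNA shares of TPM were higher in the same siGCDH libraries. Of 33 ATF4 list genes, 10 rose, 17 fell and 6 did not pass (adjusted over the list alone, 10 rose and 17 fell) (median -0.13, camera adjusted p = 2.29e-05, and adjusted p = 0.0634 with an estimated correlation). SHMT2 fell by 0.98, while DDIT3 (0.86) and TRIB3 (0.37) rose. TRIB3 and NFE2L2, which rose from 37.3 to 45.4 TPM (0.28), no longer passed after median scaling or quantile normalization. DHTKD1 did not pass (-0.14, adjusted p = 0.0853), but was lower past the threshold after that scaling. Cholesterol and SREBP genes had 3 rose and 15 fell (3 and 16 adjusted over the list alone) of 25 (median -0.28, camera adjusted p = 5.45e-08, and adjusted p = 0.104 with an estimated correlation), with SCD at -1.44, ACLY at -1.04 and IDI1 at -0.98. Respiratory chain genes had 4 rose and 13 fell (4 and 13 adjusted over the list alone) of 31 (median -0.09, camera adjusted p = 7.29e-06, and adjusted p = 0.0634 with an estimated correlation), with NDUFA2 (-1.06) and UQCRC1 (-0.72) lower and NDUFB10 (0.87) higher. MAPK output genes had 2 rose and 6 fell (2 and 5 adjusted over the list alone) of 17 (median -0.29, camera adjusted p = 0.00438, and adjusted p = 0.233 with an estimated correlation), with EPHA2 at -1.25 and DUSP5 at -0.90. Heat shock genes had 3 rose and 6 fell (3 and 6 adjusted over the list alone) of 16 (median 0.02, camera adjusted p = 0.0386, and adjusted p = 0.233 with an estimated correlation) and a mean of -0.13, with HSP90AB1 at -0.52, HSPD1 at -0.58 and HSPB1 at 0.64. The respiratory chain and heat shock calls were lost with quantile normalization.

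Of 24 p53 targets in SKBR3, 18 rose, 1 fell and 5 did not pass (adjusted over the list alone, 19 rose and 1 fell), with DDB2 at 1.35 and CCNG1 at -0.65, but the list did not pass against the other genes (camera adjusted p = 0.0881). NRF2 targets had 13 rose and 9 fell (14 and 9 adjusted over the list alone) of 27, with a median of 0.23, a mean of -0.01 and a test pointing down (camera adjusted p = 0.146). Here the autophagy receptor gene SQSTM1 rose from 75.2 to 199 TPM (1.39), while PRDX1 fell from 903 to 620.5 TPM (-0.54). Interferon genes had 8 rose and 0 fell (8 and 0 adjusted over the list alone) of 13 (camera adjusted p = 0.268), with ISG15 at 1.45, IFI6 at 1.52 and STAT2 at 0.82. Counts of rises and falls in the other lists that did not pass, with those adjusted over the list alone in parentheses, were 5 and 6 (5 and 6) of 20 for lysine and tryptophan breakdown, 11 and 4 (11 and 4) of 26 for ER chaperones, 9 and 3 (10 and 3) of 19 for pro-apoptotic genes and 5 and 1 (5 and 1) of 9 for anti-apoptotic genes. They were 15 and 9 (15 and 9) of 36 for cell cycle genes, 3 and 0 (3 and 0) of 7 for NF-kB genes, 14 and 5 (14 and 5) of 27 for glycolysis and hypoxia genes and 16 and 2 (16 and 2) of 26 for autophagy genes. The remaining counts were 7 and 0 (7 and 0) of 12 for melanocyte genes, 3 and 3 (3 and 2) of 15 for invasive melanoma genes and 4 and 0 (4 and 0) of 9 for breast marker genes. Of the cell cycle list MKI67 (0.98), KIF11 (0.75) and TOP2A (0.72) were the most significant (camera adjusted p = 0.687). Among the apoptosis lists TNFRSF10B (0.96), BID (0.72), BIRC5 (0.60) and BIRC2 (0.48) rose, and PMAIP1 (-0.88) and MCL1 (-0.84) fell. DERL3 (1.94) and HYOU1 (0.54) rose and HSP90B1 (-0.38) fell. Of the glycolysis and hypoxia list LDHA (-0.73), ENO1 (-0.66) and NDRG1 (-1.46) were the most significant and fell, while the list had a median of 0.23 (camera adjusted p = 0.893). BECN1 (0.72) of the autophagy list rose, as did ETFDH (0.80) of the electron-transfer pathway. As single genes, PMEL (from 3.49 to 11.8 TPM, 1.51), GPNMB (from 0.507 to 4.96 TPM, 2.0) and APOA1 (from 0.313 to 3.97 TPM, 1.92) rose from low levels and SOX9 fell (from 5.16 to 1.27 TPM, -1.44), their lists being not called or not tested. Camera pointed down for the lysine, ER, apoptosis, cell cycle, glycolysis and invasive melanoma lists, whose medians lay above 0, and passed for none of them.

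Only a test of the difference shows whether lines responded differently, and A375 batch 2 shares its library kit with SK-Hep1 and SKBR3. Between A375 batch 2 and SK-Hep1 the effect differed for 7183 of 15548 genes, 2698 higher and 4485 lower in A375 (median -0.14; 3499 and 3424 after median scaling). The ATF4 list differed toward A375 (median 0.39, camera adjusted p = 4.60e-05, and adjusted p = 0.0318 with an estimated correlation), with ATF3 higher by 2.55 (SE 0.21, adjusted p = 3.05e-06), CHAC1 by 1.47 and ATF4 by 0.88. NF-kB genes (median 0.65, camera adjusted p = 2.44e-05, and adjusted p = 0.0119 with an estimated correlation) and cholesterol genes (median 0.59, camera adjusted p = 2.72e-10, and adjusted p = 0.0119 with an estimated correlation) also differed upward in A375. NRF2 targets did not pass as a list against the other genes (median -0.23, camera adjusted p = 0.467, and adjusted p = 0.535 with an estimated correlation). The effect was higher in A375 for 9 and lower for 15 of 32 members. HMOX1 differed by 4.04 (SE 0.15, adjusted p = 9.50e-09), ELF3 by 3.72, PEG10 by 3.49, SNHG25 by 3.39 and RNA5SP244 by 4.37. Lower in A375 were the effects on TRPV2 (-3.85), PRR11 (-3.14), PRR11-AS1 (-2.9), DEPDC1 (-2.81) and ZNF185 (-2.77). GCDH itself fell further in A375, with a difference of -0.74 (SE 0.15, adjusted p = 0.00239).

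Between A375 batch 2 and the libraries labelled SKBR3 the effect differed for 8643 of 16820 genes, 2447 higher and 6196 lower in A375 (median -0.26, with 3414 and 4668 after median scaling, and 3858 and 3787 after quantile normalization). The ATF4 list differed by a median of 0.42 (camera adjusted p = 1.41e-10, and adjusted p = 0.00103 with an estimated correlation), with the effect higher in A375 for 20 and lower for 2 of 34 members (20 and 2 adjusted over the list alone). ATF3 differed by 3.24 (SE 0.08, adjusted p = 5.58e-10), CHAC1 by 3.16 and ATF4 by 1.12, while TRIB3 (adjusted p = 0.265), NFE2L2 (0.465) and GCDH (0.076) did not pass. Mitochondrially encoded genes differed by a median of -1.42 (camera adjusted p = 1.55e-10, and adjusted p = 0.106 with an estimated correlation). NRF2 targets did not pass (median -0.48, camera adjusted p = 0.147, and adjusted p = 0.283 with an estimated correlation). Among their 32 members the effect was higher in A375 for 5 and lower for 19. The largest single differences were MIR6807 (4.94), KRTAP2-3 (3.98), SNHG29 (3.73), HMGA2 (3.6) and RNA5SP244 (3.46) in the direction of A375. In that of SKBR3 they were HSPE1P3 (-3.77), DHX35-DT (-3.76), STAM-DT (-3.72), EIF5-DT (-3.62) and LINC01976 (-3.45). Line and culture changed together in both of these comparisons and cannot be separated.

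Called genes were then compared between the 4 within-line comparisons, which share no control libraries. The A375 batches shared 88 higher genes, where independent lists would share 25.2, and 486 lower genes against 154 (Fisher's exact test, odds ratios 9.74 and 7.56, adjusted p = 1.03e-33 and 2.91e-157). Fisher's test treats genes as independent, which they are not, so its p-values here do not measure the spread between replicates. SK-Hep1 and SKBR3 shared 1331 lower genes against 415 (odds ratio 13) and 3417 higher genes against 2300 (odds ratio 4.50). A375 batch 2 shared 566 lower genes with SK-Hep1 against 421 (odds ratio 1.60) and 545 with SKBR3 against 386 (1.71). It shared 1107 higher genes with SK-Hep1 against 920 (1.48) and 1152 with SKBR3 against 1080 (1.17). A375 batch 1 shared 250 lower genes with SK-Hep1 against 162 (1.88) and 318 with SKBR3 against 156 (odds ratio 3), and 58 higher genes with SK-Hep1 against 45.7 (1.55). Its 54 higher genes shared with SKBR3 against 48 did not pass (1.26, adjusted p = 0.243). Spearman correlations of log2 fold changes across genes, which are not independent replicates, were 0.472 between the A375 batches, 0.523 between SK-Hep1 and SKBR3, and between 0.0775 and 0.111 for the 4 pairs of A375 with another line. Genes called in both A375 batch 2 and SKBR3 numbered 3012, of which 1315 moved in opposite directions. Whether all lines received the same siRNAs is not given in the labels, so these overlaps cannot be assigned to the line alone.

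**Figure D3:**
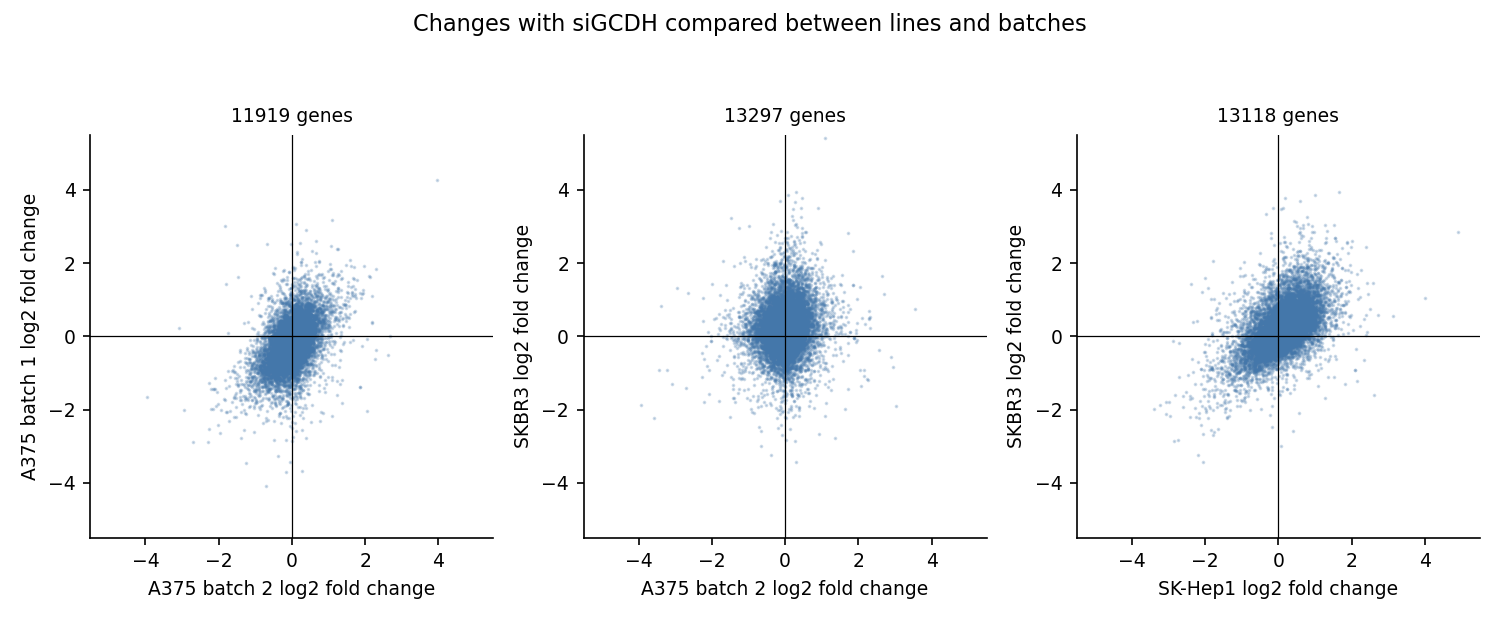
Log2 fold changes with siGCDH, each point a gene tested in both comparisons, for A375 batch 2 against A375 batch 1 (11919 genes), A375 batch 2 against SKBR3 (13297 genes) and SK-Hep1 against SKBR3 (13118 genes). The points follow a common diagonal in the first and last panel, with Spearman correlations of 0.472 and 0.523, and not in the middle panel, with 0.106.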

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

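Of the tests below, those of different siRNAs, of scaling of the ATF4 list and of seed sites in its members were chosen after the result was seen, the bounds of the last 2 being set before their values were, and that of other splits of the libraries was chosen before. Each value here is a difference between the effects of siGCDH in 2 sets of libraries that passed its interaction test, in limma for genes and camera for lists.

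Between the A375 batches 772 genes differed, a count that ran from 261 to 1190 with 1 library left out and was 225 without the trend. Of the named genes the effect was higher in batch 2 for HEXIM2-AS1 (3.62), RNF166 (3.38), IGKV1OR9-2 (3.34), MIR6807 (3.04) and SSX2 (2.87), and lower for RPL32P24 (-3.19), MCEE (-2.2), PRR11-AS1 (-1.99), CKMT2-AS1 (-1.99) and L3MBTL3 (-1.77). IGKV1OR9-2 and MIR6807 may not have been detected in batch 1, so their differences may not be differences of response. Lists differed by medians of 0.309 for the ATF4 response, 0.347 for glycolysis, 0.371 for oxidative phosphorylation and 0.431 for mitochondrially encoded genes, beside a median of 0.19 over all genes. None of these 4 lists passed with an estimated correlation (lowest adjusted p = 0.0803).

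Between A375 batch 2 and SK-Hep1 7183 genes differed. The effect was higher in A375 for RNA5SP244 (4.37), HMOX1 (4.04), ELF3 (3.72), PEG10 (3.49) and SNHG25 (3.39), and lower for TRPV2 (-3.85), PRR11 (-3.14), PRR11-AS1 (-2.9), DEPDC1 (-2.81) and ZNF185 (-2.77). Of the panel GCDH differed by -0.74, NFE2L2 by 0.25, ATF4 by 0.88, ATF3 by 2.55, DDIT3 by 0.69, CHAC1 by 1.47 and TRIB3 by 0.85. Lists differed by medians of 0.39 for the ATF4 response, 0.192 for ER chaperones, -0.449 for cell cycle, 0.654 for NF-kB, 0.594 for cholesterol synthesis, -0.342 for oxidative phosphorylation, 0.447 for invasive melanoma and 0.378 for breast markers. The ATF4 (adjusted p = 0.0318), NF-kB and cholesterol lists (both 0.0119) passed with an estimated correlation as well, adjusted over the 21 lists of this comparison and not over the 84 tests used within lines.

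Between A375 batch 2 and the libraries labelled SKBR3 8643 genes differed. The effect was higher in A375 for MIR6807 (4.94), KRTAP2-3 (3.98), SNHG29 (3.73), HMGA2 (3.6) and RNA5SP244 (3.46), and lower for HSPE1P3 (-3.77), DHX35-DT (-3.76), STAM-DT (-3.72), EIF5-DT (-3.62) and LINC01976 (-3.45). Of the panel ATF4 differed by 1.12, ATF3 by 3.24, DDIT3 by 0.49 and CHAC1 by 3.16. Lists differed by medians of 0.416 for the ATF4 response, 0.133 for p53 targets, 0.0236 for cholesterol synthesis, 0.346 for MAPK output, 0.207 for heat shock, -1.42 for mitochondrially encoded genes and -1.06 for non-polyadenylated histone genes, beside -0.26 over all genes. Of these only the ATF4 list passed with an estimated correlation (adjusted p = 0.00103).

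The ATF4 list rose in A375 batch 2 and fell in the libraries labelled SKBR3, with a median difference of 0.416 over 34 members (camera adjusted p = 1.41e-10). With an estimated correlation neither change within a line passed (adjusted p = 0.0593 and 0.0634), and the difference did (0.00103), the former being adjusted over 84 tests and the latter over 22. After median scaling the difference was 0.57 (camera adjusted p = 7.19e-11). This cannot decide on scaling as a cause, since camera compares the list with other genes and scaling shifts nearly all genes alike. The difference was 0.37 (camera adjusted p = 5.08e-08) over the 23 members without seed sites. Such sites are therefore argued against as the whole cause. The 7-mer ACTGAGA, carried by genes with lower average fold changes in A375, had a z of 1.12 in SKBR3, and no line showed both 7-mers. Different siRNAs may thus have been used, and their effect on this list cannot be told apart from that of the line. A difference between melanoma and other cells therefore stays open and untested.

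Other splits of the same libraries were also fitted. The 10 splits of 6 libraries within a line are too few for a share under 0.05. The real value and the highest other were 1018 and 3 in A375 batch 1, 5099 and 4 in batch 2, 8076 and 1 in SK-Hep1, and 10236 and 1 in SKBR3. For both A375 batches together, 1 of 100 splits, the real one, gave 3463 genes, and the highest other, 772, exchanged the labels of 1 batch. A random labelling of these wells is therefore argued against for this effect over both batches. The splits cannot tell the siRNA from another difference between the groups of wells, since both follow the labels. For the difference between the batches 1 of 100 gave 772, the highest other being 690, and no split exchanged all labels of 1 batch. These splits break the treatment labels within each batch, so they cannot decide whether the effects in the batches differ. For A375 batch 2 against SK-Hep1 2 of 100 splits reached the real 7183, the other with 7797 being the split that exchanges all labels of 1 line, and the highest apart from it was 4431. Against SKBR3 2 of 100 reached 8643, the other likewise with 9296, and the highest apart from it was 5495. Splits that mix the treatment labels lose the treatment effect itself. They therefore cannot decide whether the effects differ between lines. An exchange of all labels of 1 line turns the difference of the effects into their sum, so it holds the treatment in both lines.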

How the results depend on the processing

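Removal of the chromosome 21 rows or of seed-match genes, median scaling of the list tests, and the blocked and joint fits of GCDH were chosen after the data were seen, and the other settings before. The effect of siGCDH on GCDH was downward under every setting run, and the counts of A375 batch 2, SK-Hep1 and SKBR3 stayed within 1.5 times their value under other pseudocounts, filters, scalings, eBayes settings and the block. The depth of the libraries is unknown, so that its limit on low genes cannot be stated.

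The count of A375 batch 1 (1018) was the least stable. It was 590 with no filter, 516 with quantile normalization, 495 with median scaling, 85 without the trend, 522 with the chromosome 21 rows removed and 5558 in the joint fit of all 24 libraries, which lends it the smaller spread of the other groups. In the joint fit GCDH in batch 1 had -1.424 and passed. A375 batch 2 gave 2802 in the joint fit. Ranking by size alone, which by construction leaves out small changes, gave 534 in A375 batch 2, 1282 in SK-Hep1 and 2557 in SKBR3. The difference between the A375 batches (772, of which 706 higher in batch 2) fell to 222 genes with quantile normalization (100 higher), 185 with median scaling (102), 225 without the trend and 184 without the chromosome 21 rows (73). In SKBR3 and in its difference from A375 batch 2 the excess of 1 direction was likewise absent with quantile normalization. Beyond what construction shows, the cause was not tested.

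Same-numbered replicates shared only a number: correlations of their deviations ran from -0.0275 to 0.0567, and at most 1 of the 3 numbers in a comparison correlated best with its own. With the replicate number as a block the count of A375 batch 1 was 357 and that of the difference between the batches 243, and the lists past the threshold numbered 26. The block uses up residual degrees of freedom, and no other count of calls moved by over 1.5 times.

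Leaving out 1 library at a time gave 311 to 592 genes in A375 batch 1, each of the 6 libraries moving the count by over 1.5 times, and 261 to 1190 for the difference between the batches. There the count rose to 1190 without siControl replicate 1 of batch 1 and lay between 261 and 327 without any single library of batch 2. Fewer libraries enter such a fit, and no further cause was tested. Ranges elsewhere were 3822 to 4533 in A375 batch 2, 6983 to 7668 in SK-Hep1, 9148 to 9399 in SKBR3, 2577 to 3800 for both A375 batches, 6602 to 6884 for A375 batch 2 against SK-Hep1 and 7884 to 8322 against SKBR3. GCDH ran from -1.845 to -1.109 in A375 batch 1, from -2.265 to -2.154 in batch 2, from -1.571 to -1.378 in SK-Hep1 and from -1.948 to -1.64 in SKBR3.

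Of the 84 list tests 28 passed by camera with its preset correlation, 0 with an estimated correlation and 61 by fry, against 25 after quantile normalization, 30 after median scaling and 27 to 30 with a library left out. Without seed-match genes 22 passed, 7 upward and 15 downward, and the anti-apoptotic list, left with fewer than 5 members, was not tested in any line. That setting ended the calls of non-polyadenylated histone genes in A375 batch 1, SK-Hep1 and SKBR3, of interferon genes in A375 batch 2 and SK-Hep1, of pro-apoptotic genes in A375 batch 2 and of breast markers in SK-Hep1, and ER chaperones in A375 batch 2 passed under it. Quantile normalization ended the calls of interferon genes in A375 batch 2, breast markers and histone genes in SK-Hep1, and heat shock and respiratory chain genes in SKBR3. Fry pointed opposite to camera for the ATF4 (adjusted p = 0.00859) and MAPK (0.0449) lists in SK-Hep1 and, in SKBR3, for ER chaperones (0.00317), pro-apoptotic (0.00141), anti-apoptotic (0.0258), cell cycle (5.62e-04) and glycolysis genes (0.0026), as a test against 0 can where all genes shift. Of the values of named genes, quantile normalization turned IER3 (-4.148e-04), NFKBIA (-0.02822) and SOX18 (-0.01222) in SKBR3, 27 other calls no longer passed under it, and 25 no longer passed under median scaling. Calls no longer passing numbered 58 without the trend and 35 with the block, most of them in A375 batch 1, 20 with no filter, 17 without the chromosome 21 rows, 10 in the joint fit, 8 with a pseudocount of 0.1, 1 with a pseudocount of 5 and 1 with robust eBayes. Over all leave-one-out fits 191 calls were lost, most of them in A375 batch 1. The overlap of higher genes between A375 batch 1 and SKBR3 passed with a filter of 5 TPM (odds ratio 1.47), and that between batch 1 and SK-Hep1 no longer passed over calls of at least 0.5 on the log2 scale (1.3). The causes were not tested.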

Other observations

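The tests of seed matches in the other comparison of each pair, of orders that share no run of 5 bases, of a common response of the lines and of the identity of the SKBR3 libraries were chosen after the results were seen, and the test of base composition over all orders before.

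HMOX1 and HNRNPC were followed across all comparisons, a choice made after their values were seen. HMOX1, which encodes the heme-degrading enzyme heme oxygenase, rose in A375 batch 2 (from 40.0 to 86.2 TPM, 1.09), fell in SK-Hep1 (from 41.4 to 4.54 TPM, -2.95) and fell in SKBR3 (from 25.1 to 4.88 TPM, -2.17), with differences of 4.04 and 3.26 between A375 batch 2 and these lines (limma adjusted p = 9.50e-09 and 8.11e-08). In A375 batch 1 it had 0.24 and did not pass (adjusted p = 0.525). HMOX1 belongs to the NRF2 list, and its 3' UTR holds ATCCTCA. HNRNPC fell in each comparison, with -2.88 and -2.71 in the A375 batches, -0.51 in SK-Hep1 and -1.42 in SKBR3 on the log2 scale, and fell further in A375 batch 2 than in SK-Hep1 (difference -2.2) or SKBR3 (-1.29). Its 3' UTR holds TCCTCAA and not ACTGAGA.

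Genes with a certain 7-mer in their 3' UTRs had lower fold changes on average than genes without it. This 7-mer was ACTGAGA in A375 and ATCCTCA in the other lines. The mean differences were -0.168 and -0.138 log2 units in A375 batches 2 and 1, -0.219 in SK-Hep1 and -0.199 in SKBR3. Several of the largest falls held no such site, among them HNRNPC and CCL2 in A375 batch 2 and RPL13A in SKBR3. ACTGAGA had the lowest z of 15931 7-mers in A375 batch 2 (-15.7) and -7.79 in batch 1, and ATCCTCA had -13.1 in SK-Hep1 and -12.8 in SKBR3, the shifted 7-mers CTGAGAA and TCCTCAA reaching -14.0 in batch 2 and -16.0 in SK-Hep1. The z of ACTGAGA was -0.645 in SK-Hep1 and 1.12 in SKBR3. These values argue against a common response of the lines to less GCDH as the cause of the ACTGAGA pattern. They do not bear on other changes that the lines share. The bound set beforehand against base composition, that 3 times the z of any other order of the same bases stay above the z of the site, was not met, the lowest being -5.99 and -4.51 in A375 batches 2 and 1, -8.45 in SK-Hep1 and -8.52 in SKBR3. With orders sharing a run of 5 bases left out the lowest were -2.44 in A375 batch 2 and -3.58 in SK-Hep1, within that bound, but -4.0 in A375 batch 1 and -5.29 in SKBR3, outside it. Base composition is therefore argued against as the whole cause in A375 batch 2 and SK-Hep1, and a part of it stays open in A375 batch 1 and SKBR3. A candidate explanation is that siRNAs with different seeds were used in A375 and in the other lines and lowered transcripts with a matching 3' UTR. ACTGAGA lies in exon 10 of 12 of GCDH-201 (hg38 chromosome 19, 12897367 to 12897373) and ATCCTCA in exon 4 (12891896 to 12891902). Each was chosen as the 7-mer of lowest z that lies in this mRNA. ACTGAGA was also the lowest of all in A375 batch 2. ATCCTCA ranked 2 in SK-Hep1 behind TCCTCAA, so its place in the mRNA is by construction. Of all 7-mers 10.876% lie in that mRNA and the shifted pair does not, and the labels give no siRNA sequence.

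The libraries labelled SKBR3 held little RNA of breast epithelial markers. With siControl ERBB2 was at 25.5 TPM, a ratio of 0.55 to the higher of the other lines of the same kit, GRB7 was at 0.513 TPM and KRT7 at 0.0767 TPM, whereas IRS4 (301.5 TPM), CA2 (301.8 TPM), LIN28B (47.0 TPM) and CDKN2A (370.3 TPM), chosen after their values were seen, were high. Loss of the markers through siGCDH is argued against, since ERBB2 was as low with siControl (25.5 TPM) and at 41.6 TPM with siGCDH, and RNA of A375 or SK-Hep1 is argued against by SOX10 and KRT19, of which the higher reached 0.018% of its level in those lines. That the libraries come from another cell line than the label says is a hypothesis that this ratio of 0.55 is consistent with. No genotype was analysed here, and a subline that lost these markers stays open.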
